A study of Homo sapiens with 18 samples.

How the data were processed

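Gene expression was measured in 18 libraries of A375 cells, 3 in each of 6 groups. Per the labels' protocols, cells were plated in 6-well plates and left overnight before IMD-0354 was added, total RNA was isolated with a GenElute kit and an on-column DNase step, and libraries were made with the QuantSeq 3' mRNA-Seq kit (FWD, Lexogen). Per the submitters' processing notes, cutadapt 1.18, STAR 2.7, RSEM 1.3.1 and DESeq2 were used, with no role stated for each; the genome build and annotation are not given in the sources used here. The authors deposited 1 table of TPM per gene, with 60504 Ensembl identifiers and 1 column per library. Each column had the same sum within rounding, from 999999.1 to 1000000.5. TPM holds no read counts, so no test on counts was made, depth could not be given, and the precision that depth allows is unknown. TPM is divided by transcript length, while 3' end libraries yield about 1 tag per transcript whatever its length. This factor raises the level printed for very short RNAs, such as small nuclear and Y RNAs, over that of mRNAs. Whether it was constant for a gene between libraries could not be checked, nor how fully such short RNAs were captured.

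Gene symbols came from a table of Ensembl identifiers, which matched 56558 of the identifiers and gave a symbol for 41209; coordinates are those of GENCODE release 29 (GRCh38), matched by identifier for 56996 genes. In all, 35856 genes were at 0 in every library. Genes with at least 1 TPM in at least 3 of the 18 libraries were kept, 14936 in number and 13367 with a symbol, and log2(TPM + 1) was computed from the deposited TPM. R 4.3.3 with limma 3.58.1 and statmod 1.5.0 was used. One linear model with a mean per group was fitted to all 18 libraries (12 residual degrees of freedom), followed by empirical Bayes moderation with a mean-variance trend (4.16 prior degrees of freedom). Each dose was tested against the untreated libraries of its time. Neighbouring doses at 24 h, a linear trend over dose, the difference between the effects of 0.63 µM at 48 and 24 h, and untreated cells at 48 against 24 h were also tested. Genes with a Benjamini-Hochberg adjusted p under 0.05, with both directions tested, were called.

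The 37 gene lists, with 903 members of which 800 were measured, were written before the data were examined, as were the tests, the filter, the rule for naming genes and most of the alternatives. The 31 lists with at least 5 measured members were tested with camera in limma, with a preset correlation between genes of 0.01 and adjustment over the lists of a comparison, and again with an estimated correlation and with fry; over the 4 comparisons with untreated cells this made 124 list tests. Lists of non-coding snoRNA hosts, nonsense-mediated decay factors, iron handling and replication-dependent histones were added after the data were seen. For each dose comparison, named genes were the 8 largest rises and the 8 largest falls among genes with a symbol that passed, had a mean of at least 5 TPM in 1 of the groups and did not overlap between the groups. For the other tests the first 5 in each direction were named, and for each list up to 4 members that passed with the largest change, or where fewer than 2 passed the 2 with the largest change. A preset set comprised IKBKB, CHUK, IKBKG, RELA, NFKB1, NFKBIA, MITF, SOX10, MLANA, MKI67, CCND1, CDKN1A, MYC, HMOX1, ATF3, DDIT3, TRIB3, TXNIP, PPARGC1A, BRAF, DUSP6, HMGCS1 and GDF15; PPARGC1A was below the filter. Agreement between comparisons was described by correlations across genes and by shared calls, beside values from 100 simulations of unchanged groups with shared controls for the doses at 24 h.

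The procedure was tested on simulated data with 14936 genes, 100 of them changed at each of 2 sizes and a list of 30 shifted by 0.7. For 1.25 µM at 24 h it recovered 18% of genes changed by 1 and 69% of genes changed by 2 on the log2 scale, with 95 calls, 4 of them false and 4 of them genes of the shifted list. For 0.63 µM at 48 h it recovered 24% and 74%, with 105 calls, 7 of them false and none in the shifted list. Of 200 unchanged lists 4 had a camera p under 0.05 in each of these comparisons. The simulated genes were independent of one another, so this cannot show how camera behaves on lists of correlated genes. The alternatives set at that time were a pseudocount of 0.1 or 5 TPM, no filter or a minimum of 5 TPM, median-of-ratios scaling, quantile normalization, no mean-variance trend, a robust prior, only the compared groups in the fit, the replicate number as a block, library weights, and leaving out each library. Alternatives chosen after seeing the data left out 2 libraries with the lowest mean correlation to their group (untreated 24 h replicates 2 and 3), left out 2 libraries picked by eye (untreated 24 h replicate 2 and 0.63 µM 24 h replicate 3), or rescaled TPM without 4 abundant chromosome 21 transcripts. The results of 4 single genes are not reported here, though these genes stay in the counts and lists. Reads were not analysed here, and no library was left out of the main results.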

Results

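The transcriptome of A375 cells, an established human melanoma line that carries an activating BRAF mutation, was measured by 3' end RNA sequencing after exposure to IMD-0354, a small molecule described as an inhibitor of the kinase IKKβ in the NF-κB pathway. The 18 libraries formed 6 groups of 3. Cells were left untreated or received 0.32, 0.63 or 1.25 µM for 24 h, and a further pair of groups was left untreated or received 0.63 µM for 48 h. The labels name no vehicle for the untreated cells. Nothing in them says that the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Values were TPM, transcript levels scaled to a fixed total per library. They keep no record of sequencing depth, so the depth of each library is unknown. Between 14647 and 17029 genes had a value above 0 in a library, and 14936 genes were tested. No pair of libraries was identical among 153 pairs, and Pearson's r across genes ran from 0.866 to 0.956; genes are not independent replicates. Fold changes are on the log2(TPM + 1) scale, with the standard error (SE) of the fit, and understate the change of genes with low values. Group levels are means ± SD (n = 3).

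At 0.32 µM for 24 h none of the stress, cell cycle and NF-κB genes named here passed the test. DDIT3, which encodes the stress-induced transcription factor CHOP, stood at 16.1 ± 5.28 TPM against 14.9 ± 3.06 TPM in untreated cells. TRIB3, a pseudokinase gene driven by ATF4 and CHOP, was at 19.3 ± 1.73 against 14.04 ± 3.65 TPM (adjusted p = 0.832), and MKI67, which encodes the proliferation marker Ki-67, at 114 ± 21.9 against 111 ± 31.8 TPM. The question was whether the lowest dose altered expression, and limma called 1 gene higher and 3 lower, while 912 genes had an unadjusted p under 0.05. The 4 genes lay outside the rule for naming and were looked up after their values were seen. They were TPM3P6 (2.11), NANOS1 (-1.88), ENSG00000248155 (-2.25) and ENSG00000252236 (-2.86), each under 7 TPM. With only the compared groups in the fit limma called 0 genes, as it did without the 2 libraries least correlated with their group. The count was 2 without untreated replicate 3 and 1 without 0.32 µM replicate 1.

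Transcripts encoded by mitochondrial DNA formed 1 of the 2 lists shifted at 0.32 µM. None of the 13 measured members passed over all genes and 5 rose when adjusted over the list alone, with a median of 0.46 (camera adjusted p = 3.21e-08; adjusted p = 0.766 with an estimated correlation). MT-ATP6, a subunit of ATP synthase, stood at 6600 ± 259 against 3166 ± 1216 TPM. The share of all TPM held by these 13 transcripts was 5.13% ± 0.147 at 0.32 µM, 3.31% ± 1.13 in untreated cells, 4.92% ± 1.98 at 0.63 µM and 4.13% ± 1.03 at 1.25 µM at 24 h, and at 48 h it was 2.81% ± 0.412 untreated and 2.90% ± 0.435 at 0.63 µM. Without the 2 least correlated libraries, untreated 24 h replicates 2 and 3, the list gave an adjusted p of 0.821 at 0.32 µM. The other list held oxidative stress genes controlled by NRF2. Of its 25 measured genes 0 passed over all genes and 1 rose when adjusted over the list alone, with a median of 0.29 (camera adjusted p = 0.00252; adjusted p = 0.766 with an estimated correlation). The other 29 lists tested at this dose did not pass, and no member of any of them passed by itself or when adjusted over the list alone. Quantile normalization brought tRNA synthetases (0.0401), glycolysis (0.0337), complex I (0.00294) and complexes II to V (0.0401) under 0.05 at this dose. Without untreated replicate 3 glycolysis (0.00278), complex I (0.00278) and complexes II to V (0.026) also passed. Complex I passed without untreated replicate 1 (0.0279) and 0.32 µM replicate 3 (0.0353), cholesterol synthesis without untreated replicate 2 (0.0139), and hypoxia genes without the 2 least correlated libraries (0.0246).

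**Figure D1:**
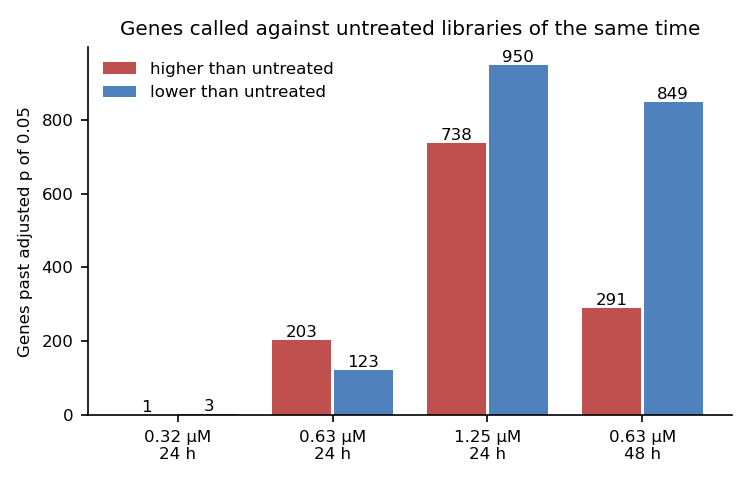
Number of genes past an adjusted p of 0.05 (y axis) in each IMD-0354 group against the untreated libraries of the same time (x axis), with genes higher than untreated in red and genes lower in blue. The count was 4 at 0.32 µM, 326 at 0.63 µM and 1688 at 1.25 µM for 24 h, and 1140 at 0.63 µM for 48 h.

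At 0.63 µM for 24 h, genes of the integrated stress response rose and chaperone genes of the heat shock response fell. DDIT3 rose by 3.01 (SE 0.356, adjusted p = 0.000407), from 14.9 ± 3.06 to 144 ± 97.4 TPM. PPP1R15A, whose product directs the dephosphorylation of eIF2α, rose by 2.20 (SE 0.178, adjusted p = 1.84e-05), from 19.7 ± 2.93 to 94.9 ± 22.4 TPM. GDF15 (ENSG00000130513, chromosome 19, 18374731 to 18389176, plus strand, protein coding), a secreted stress cytokine, had the largest rise, 4.30 (SE 0.576, adjusted p = 0.00125). IL24, a cytokine gene of the IL-10 family, rose by 3.34 (SE 0.388, adjusted p = 0.000407) and FTH1, the heavy chain of the iron store ferritin, by 1.46 (SE 0.132, adjusted p = 3e-05), from 2643 ± 349 to 7287 ± 969 TPM.

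Of the 33 measured ATF4 targets, which the integrated stress response induces, 17 rose and 16 did not pass; 24 rose and 1 fell when adjusted over the list alone (median 1.175, camera adjusted p = 1.4e-24, kept with an estimated correlation at adjusted p = 0.0103). TRIB3 rose by 2.06 (adjusted p = 0.000177) and GTPBP2, a ribosome rescue factor, by 3.72 (adjusted p = 0.000407). DDIT4, an inhibitor of mTORC1 held here on the hypoxia list, rose by 1.67. It was the 1 hypoxia gene of 23 that passed. On that list 3 rose when adjusted over the list alone, and it gave a camera adjusted p of 0.129, with 0.0442 without untreated replicate 3. ATXN2L, a stress granule component, rose by 3.39. Among 20 tRNA synthetases, which charge tRNAs with amino acids, 3 rose, while 9 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.000852; adjusted p = 0.21 with an estimated correlation). Of 22 genes of the unfolded protein response of the endoplasmic reticulum 2 rose, and 3 when adjusted over the list alone (camera adjusted p = 0.218). Of 15 immediate early genes of the AP-1 class 3 rose, and 6 when adjusted over the list alone (median 0.71, camera adjusted p = 1.22e-05; adjusted p = 0.0266 with an estimated correlation).

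Heat shock genes fell at the same dose. Of 17 measured members 7 fell and 10 did not pass, and 12 fell when adjusted over the list alone (median -0.86, camera adjusted p = 1.85e-08; adjusted p = 0.0168 with an estimated correlation). HSPA1A, the stress-induced HSP70, fell by 2.93 (SE 0.524, adjusted p = 0.0119), from 79.0 ± 42.9 to 10.5 ± 7 TPM. Its near-identical neighbour HSPA1B shares sequence with it, so the division of reads between them is uncertain. The call for HSPA1A was lost without 0.63 µM replicate 3 (adjusted p = 0.0609). Of 40 genes of G2/M and mitosis 5 fell, and 18 when adjusted over the list alone (median -0.67, camera adjusted p = 5.64e-11; adjusted p = 0.226 with an estimated correlation). CCNB1, the mitotic cyclin B1, fell by 1.13 (SE 0.183, adjusted p = 0.0057), from 222 ± 18.1 to 102 ± 18.5 TPM. Of 39 E2F targets, which act in DNA replication, 0 passed over all genes in limma and 6 fell when adjusted over the list alone (median -0.51, camera adjusted p = 1.22e-05; adjusted p = 0.336 with an estimated correlation).

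Several other lists shifted upward at 0.63 µM, each lost with an estimated correlation. Of 20 genes downstream of MAPK/ERK signalling 6 rose, and 8 when adjusted over the list alone (camera adjusted p = 0.000199; adjusted p = 0.21 with an estimated correlation). Of 23 genes of dedifferentiated melanoma 5 rose, and 9 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.00185; adjusted p = 0.158 with an estimated correlation). Of 21 YAP/TEAD targets 3 rose, and 4 when adjusted over the list alone (camera adjusted p = 0.00223; adjusted p = 0.21 with an estimated correlation). Of 25 NRF2 genes 2 rose, and 4 when adjusted over the list alone (camera adjusted p = 0.000101; adjusted p = 0.318 with an estimated correlation). Of 36 genes of lysosomes and autophagy 4 rose, and 7 when adjusted over the list alone (camera adjusted p = 0.00164; adjusted p = 0.271 with an estimated correlation), and the list was lost without untreated replicate 2 (0.0533). Of 76 ribosomal proteins 2 rose, also when adjusted over the list alone (median 0.20, camera adjusted p = 2.56e-05; adjusted p = 0.336 with an estimated correlation), with RPL23A up by 0.92; this list was lost under quantile normalization (0.522).

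Mitochondrial and sterol lists passed camera at 0.63 µM but were lost without single libraries. Of the 13 mitochondrial DNA transcripts 3 rose, and 4 when adjusted over the list alone (median 0.42, camera adjusted p = 0.00198; adjusted p = 0.471 with an estimated correlation). Its adjusted p was 0.275 without untreated replicate 3, 0.0775 without 0.63 µM replicate 1 and 0.0646 without 0.63 µM replicate 2, and without the 2 least correlated libraries the direction turned (median -0.26, adjusted p = 0.927). Of 37 nuclear genes of complex I 0 passed over all genes in limma or when adjusted over the list alone (median 0.18, camera adjusted p = 0.0378; adjusted p = 0.501 with an estimated correlation), and the adjusted p was 0.953 without untreated replicate 2, 0.118 without 0.63 µM replicate 1 and 0.059 without 0.63 µM replicate 2. Of 39 genes of complexes II to V 2 rose, and 3 when adjusted over the list alone (camera adjusted p = 0.00634; adjusted p = 0.336 with an estimated correlation; 0.0706 without untreated replicate 2). Rescaling without 4 abundant chromosome 21 transcripts also ended both nuclear calls (0.123 and 0.0566). Of 25 genes of cholesterol synthesis 0 passed over all genes in limma or when adjusted over the list alone (median -0.19, camera adjusted p = 0.0437; adjusted p = 0.336 with an estimated correlation), with 0.589 without untreated replicate 3, 0.059 without 0.63 µM replicate 2 and 0.072 without 0.63 µM replicate 3.

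The remaining lists did not pass camera at 0.63 µM. The p53 targets had 1 of 25 higher, and 4 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.681). Genes of ribosome biogenesis driven by MYC had 1 higher and 2 lower of 30, and 2 higher and 3 lower when adjusted over the list alone (0.544; median 0.01, mean -0.06, with the median turning negative under each of 3 scalings). Genes of TGF-β signalling and matrix had 2 of 24 higher, also when adjusted over the list alone (0.149). No member passed over all genes for glycolysis (19 genes, 0.0697, with 0.026 under quantile normalization and 0.0376 and 0.00251 without untreated replicates 1 and 3), fatty acid synthesis (12, 0.957), mitochondrial biogenesis (18, 0.957), melanocyte and pigment genes (13, 0.938), starvation genes of FOXO and AMPK (12, 0.647), apoptosis regulators (24, 0.957), interferon response (21, 0.168) and antigen presentation (18, 0.0697, with 0.00902 without untreated replicate 3 and 0.0389 without 0.63 µM replicate 2). When adjusted over the list alone 1 fatty acid gene and 1 interferon gene fell, 2 starvation genes rose, 1 biogenesis gene rose and 1 fell, and no gene of the other 4 lists passed.

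Limma called 203 genes higher and 123 lower at 0.63 µM, of which 146 and 92 changed at least 2-fold, and 2672 genes had an unadjusted p under 0.05. The count rested on the spread pooled over all 6 groups, since limma called 0 genes with only the compared groups in the fit, and it was 21 without untreated replicates 2 and 3. It was 142 without untreated replicate 2, 490 without untreated replicate 3, and 142, 161 and 51 without 0.63 µM replicates 1, 2 and 3. In replicate 3 GDF15 stood at 284 TPM and DDIT3 at 256 TPM, against 43.7 and 57.0 TPM and 91.9 and 83.7 TPM in the other libraries. Of 60 named genes past the threshold 13 kept the call with each library left out, and 7 with every alternative but the fit restricted to the compared groups. Among genes that the naming rule chose, S100P (4.02; ENSG00000163993, chromosome 4, 6693069 to 6697170, plus strand), CHAC1 (2.90) and RASAL2-AS1 (2.83) rose, but without 0.63 µM replicate 3 their adjusted p was 0.143, 0.0797 and 0.0934. SNORA61 (-4.24), SKA2P1 (-2.56), GINS4 (-2.46), RNU4ATAC (-2.30) and H1-1 (-2.20) fell, with 0.115, 0.15, 0.15, 0.109 and 0.173 without that library, and each of these 8 calls was also lost without at least 1 other library. C1DP1 (0.108 without that library) and RNU6-1016P were listed at 0 in all 3 treated libraries. Removing the 4 chromosome 21 transcripts moved the split from 62.3% to 44.5% higher (147 higher, 183 lower).

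At 1.25 µM for 24 h genes of the integrated stress response such as DDIT3 were again higher than in untreated cells, and genes of cell division were lower. IL24 had the largest rise, 5.49 (SE 0.388, adjusted p = 4.71e-07), from 6.25 ± 2.89 to 311 ± 76.7 TPM. PPP1R15A rose by 3.46 (SE 0.178, adjusted p = 1.9e-08) to 225 ± 10.7 TPM, DDIT3 by 3.87 (SE 0.356, adjusted p = 5.99e-06) to 230 ± 19.7 TPM, and GDF15 by 5.21 (SE 0.576, adjusted p = 3.79e-05) to 175 ± 61.8 TPM. CDK1, the kinase that drives entry into mitosis, fell by 2.74 (SE 0.297, adjusted p = 3.06e-05), from 176 ± 12.4 to 27.0 ± 10.3 TPM. TYMS, thymidylate synthase, fell by 1.96 (SE 0.248, adjusted p = 0.000125), from 55.8 ± 6.89 to 13.6 ± 1.41 TPM.

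Of 40 genes of G2/M and mitosis 37 fell and 3 did not pass at 1.25 µM, and 38 fell when adjusted over the list alone (median -1.67, camera adjusted p = 6.63e-32; adjusted p = 0.0333 with an estimated correlation). ANLN, an actin binding protein of the cleavage furrow, fell by 2.51, KIF20A, a kinesin of cytokinesis, by 2.47 and AURKA, a spindle pole kinase, by 2.25. Of 39 E2F targets 21 fell, and 28 when adjusted over the list alone (median -1.17, camera adjusted p = 1.27e-15; adjusted p = 0.0671 with an estimated correlation). RRM2, a subunit of ribonucleotide reductase, fell by 2.05, MCM10, a replication initiation factor, by 2.10, and CLSPN, which mediates the replication checkpoint, by 1.91. MKI67 fell by 1.66 (adjusted p = 0.00304). Of 17 heat shock genes 8 fell, and 10 when adjusted over the list alone (median -0.67, camera adjusted p = 1.58e-06; adjusted p = 0.0333 with an estimated correlation). They included the cytosolic HSP90 gene HSP90AA1 (-1.93), the constitutive HSP70 gene HSPA8 (-1.49), CHORDC1 (-1.47) and HSPH1 (-1.35). HSPA1A, at 50.9 ± 27.3 TPM, was higher at 1.25 than at 0.63 µM.

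Of 33 ATF4 targets 14 rose at 1.25 µM, and 17 rose and 1 fell when adjusted over the list alone (median 0.75, camera adjusted p = 5.29e-13; adjusted p = 0.0333 with an estimated correlation). TRIB3 rose by 2.31 (adjusted p = 9.02e-06) and CHAC1, which degrades glutathione, by 2.62. Of 22 genes of the unfolded protein response 7 rose, and 9 when adjusted over the list alone (camera adjusted p = 0.000888; adjusted p = 0.0604 with an estimated correlation). HSPA5, the chaperone BiP, rose by 1.34 (adjusted p = 0.000124), from 183 ± 52.4 to 453 ± 18.7 TPM, HERPUD1 by 2.12 and HYOU1 by 1.43. Of 15 AP-1 genes 9 rose, and 11 when adjusted over the list alone (median 0.96, camera adjusted p = 3.82e-08; adjusted p = 0.0181 with an estimated correlation), among them MAFF (1.88) and EGR1 (1.81). Of 20 MAPK/ERK genes 6 rose, and 8 when adjusted over the list alone (camera adjusted p = 0.00368; adjusted p = 0.298 with an estimated correlation), among them the phosphatase DUSP5 (2.12) and MYC (1.99).

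Of 36 genes of lysosomes and autophagy 8 rose, and 12 when adjusted over the list alone (median 0.39, camera adjusted p = 1.01e-06; adjusted p = 0.0604 with an estimated correlation). WIPI1 (2.90) and MAP1LC3B (2.15), which act in forming autophagosomes, the lysosomal GTPase RRAGD (1.60) and the protease CTSB (1.52) rose most. Of 24 apoptosis regulators 5 rose, also when adjusted over the list alone (camera adjusted p = 0.02; adjusted p = 0.0604 with an estimated correlation), and the list was lost without untreated replicate 3 (0.0633) and without 1.25 µM replicate 3 (0.0521). HRK, a promoter of apoptosis, and BCL2A1, an inhibitor of it, were listed at 0 in the untreated libraries and stood at 4.88 ± 1.11 and 3.18 ± 1.73 TPM. BCL2L2, an inhibitor, rose by 1.60. Of 76 ribosomal proteins 20 rose, and 35 when adjusted over the list alone (median 0.32, camera adjusted p = 4.93e-13; adjusted p = 0.102 with an estimated correlation). Of the 13 mitochondrial DNA transcripts 3 rose, and 6 when adjusted over the list alone (camera adjusted p = 0.0141; adjusted p = 0.694 with an estimated correlation), led by MT-CO1 (1.73). That list was lost without untreated replicate 3 (0.293), 1.25 µM replicate 1 (0.058) or 1.25 µM replicate 2 (0.0647), and under quantile normalization (0.092). Of 37 complex I genes 5 rose and 1 fell, and 8 rose and 3 fell when adjusted over the list alone (camera adjusted p = 0.023; adjusted p = 0.681 with an estimated correlation), with 0.446 without untreated replicate 2, 0.0791 without 1.25 µM replicate 2 and 0.0617 after rescaling.

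Members of further lists moved at 1.25 µM without a shift of the list. Of 25 p53 targets 4 rose and 2 fell, and 5 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.292). The stress sensor GADD45A rose by 2.7 and the cell cycle inhibitor CDKN1A by 1.95 (adjusted p = 0.00698), while PLK2 fell by 1.73 and the DNA repair gene DDB2 by 1.19. Of 23 genes of dedifferentiated melanoma 4 rose and 5 fell, and 6 rose and 7 fell when adjusted over the list alone (0.585). THBS1, a matrix glycoprotein, fell by 2.76 (adjusted p = 5.58e-06), from 73.6 ± 9.71 to 10.2 ± 2.73 TPM, CAV1, the coat protein of caveolae, fell by 2.07 (adjusted p = 1.66e-07), and NGFR, a neural crest receptor, rose by 1.35. Of 25 NRF2 genes 3 rose and 2 fell, and 4 rose and 2 fell when adjusted over the list alone (0.365), with FTH1 up by 1.92 (adjusted p = 4.21e-07) to 9992 ± 1443 TPM. Of 23 hypoxia genes 3 rose, and 3 rose and 1 fell when adjusted over the list alone (0.396), among them NDRG1 (2.24) and the glucose transporter SLC2A3 (1.87). Of 20 tRNA synthetases 5 rose and 2 fell, also when adjusted over the list alone (0.39; 0.0499 under quantile normalization). NARS1 fell by 0.96. Of 12 starvation genes 3 rose and 1 fell, and 4 rose and 3 fell when adjusted over the list alone (0.646; median -0.14, mean 0.16, test upward), with TXNIP, an inhibitor of glucose uptake, up by 2.68.

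The other lists at 1.25 µM gave few calls. Of 39 genes of complexes II to V 3 rose and 3 fell, and 5 rose and 3 fell when adjusted over the list alone (camera adjusted p = 0.19; 0.0101 under quantile normalization). Of 18 genes of mitochondrial biogenesis 1 rose and 2 fell, and 2 rose and 2 fell when adjusted over the list alone (0.396). The mitochondrial chaperones HSPE1 and HSPD1 fell by 1.38 and 1.3. Of 30 genes of ribosome biogenesis 3 rose and 4 fell, and 3 rose and 6 fell when adjusted over the list alone (0.292), with nucleolin, NCL, down at -1.36. Of 24 TGF-β genes 3 rose and 3 fell, also when adjusted over the list alone (0.732; median -0.10, mean 0.02). Of 13 melanocyte genes 2 fell, and 2 rose and 2 fell when adjusted over the list alone (0.365). MITF was 1 of them (-0.96, adjusted p = 0.0498), lost without untreated replicates 1, 2 or 3 (0.114, 0.0658, 0.105), without 1.25 µM replicates 1 or 2 (0.119, 0.216) and under median-of-ratios scaling and quantile normalization. Cholesterol synthesis had 2 of 25 lower, 3 when adjusted over the list alone (0.396; median 0.01, mean -0.17, the median turning negative under quantile normalization and rescaling). Fatty acid synthesis had 1 of 12 lower (0.132; ACSL3, -1.35) and glycolysis 1 of 19 (0.646; median 0.02, mean 0.00, test downward, median negative after rescaling, 0.0163 without untreated replicate 2), both also when adjusted over the list alone. Antigen presentation had 1 of 18 higher and 1 lower, also when adjusted over the list alone (0.396). YAP/TEAD had 1 of 21 higher and 1 lower, also when adjusted over the list alone (0.94; median -0.14, mean 0.06, test downward). The interferon response had 1 of 21 lower and 3 when adjusted over the list alone (0.396).

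Limma called 738 genes higher and 950 lower at 1.25 µM, 492 and 613 of them at least 2-fold. In all, 3838 genes had an unadjusted p under 0.05. The largest rises also included S100P (4.95) and the uridine phosphorylase gene UPP1 (3.76). SPRR2D and LINC00520 were listed at 0 in the untreated libraries and reached 18.7 ± 5.49 and 14.7 ± 1.48 TPM. The linker histone gene H1-5 (-3.51), the small Cajal body RNA SCARNA22 (-3.43) and the Y RNA RNY3 (-4.09) fell most among genes not listed at 0. Capture of histone and small RNAs was not tested for any comparison. IGHVII-44-2, SKA2P1, H1-1, RNU6-1016P and SNORA67 were listed at 0 in every treated library, the last lost without untreated replicates 1 or 3 (0.0925, 0.0822) or any treated replicate (0.0718, 0.0743, 0.0832). SNORD3C (4.29) rose but was lost without untreated replicates 1, 2 or 3 (0.108, 0.0668, 0.0961) or 1.25 µM replicates 2 or 3 (0.15, 0.162). The count was 960 without 1.25 µM replicate 3 and 171 with only the compared groups in the fit. Of 117 named genes past the threshold, 74 kept the call with each library left out and 22 with every alternative.

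**Figure D2:**
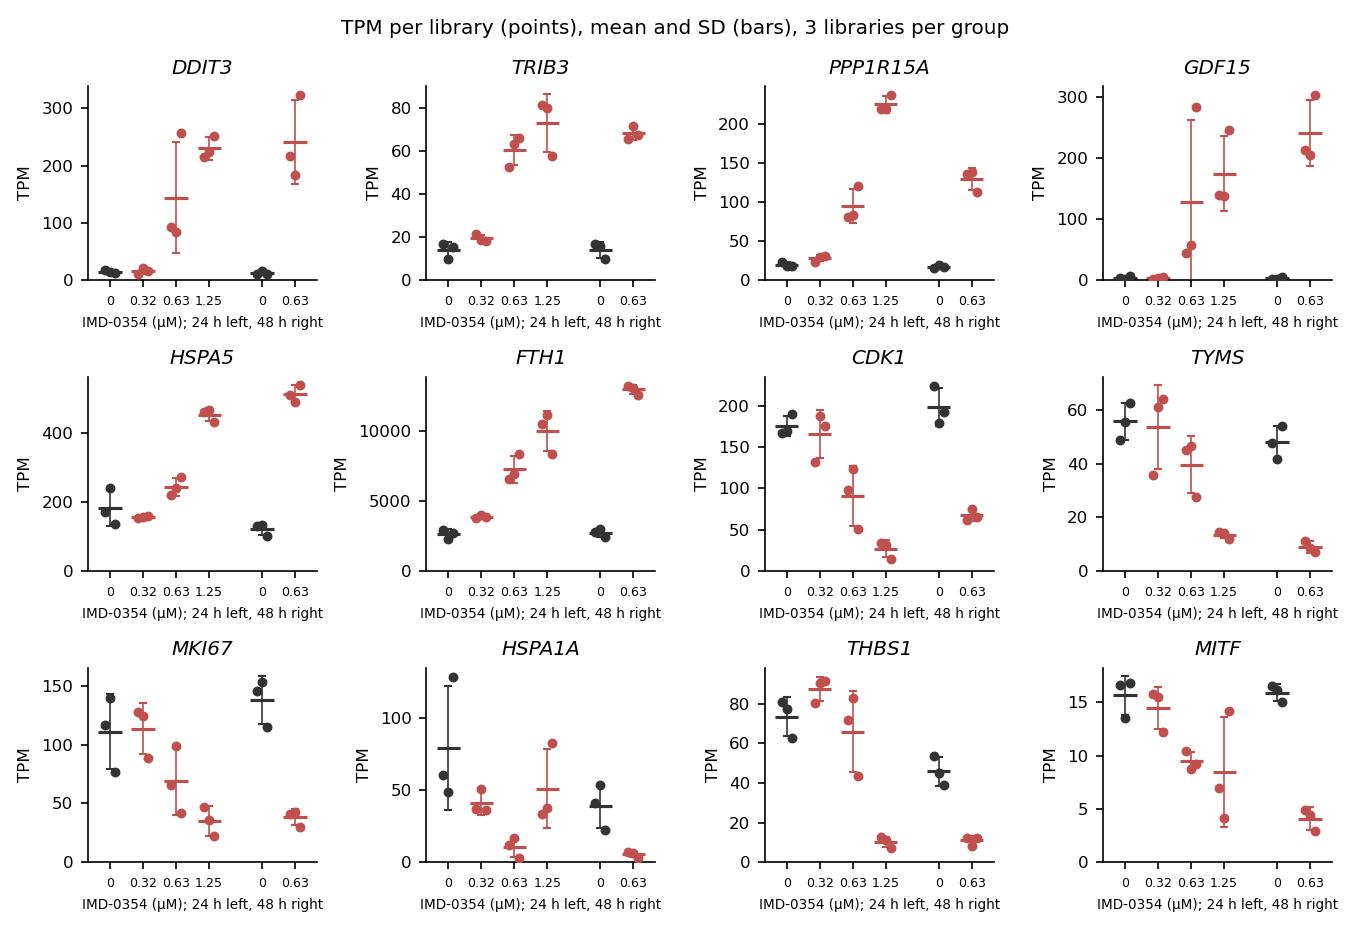
TPM of 12 genes, chosen after their values were seen, in each library (points; y axis) by IMD-0354 dose in µM (x axis), with 24 h at the left and 48 h at the right of each panel, untreated libraries in dark grey and treated libraries in red; horizontal lines are means and bars SD of 3 libraries, the lower bar of GDF15 at 0.63 µM for 24 h running below 0. DDIT3 stood at 14.9 ± 3.06 TPM untreated and 230 ± 19.7 TPM at 1.25 µM at 24 h, and CDK1 at 176 ± 12.4 and 27.0 ± 10.3 TPM.

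After 48 h at 0.63 µM, genes of the integrated stress response and the ferritin gene FTH1 were higher than in untreated cells of that time, and genes of DNA replication and mitosis were lower. GDF15 rose by 6.12 (SE 0.576, adjusted p = 1.06e-05), from 2.64 ± 1.61 to 241 ± 54.0 TPM. DDIT3 rose by 4.18 (SE 0.356, adjusted p = 4.03e-06) to 241 ± 72.9 TPM, and HSPA5 by 2.07 (SE 0.170, adjusted p = 3.47e-06), from 123 ± 17.1 to 515 ± 25.3 TPM. FTH1 rose by 2.24 (SE 0.132, adjusted p = 1.54e-07), from 2752 ± 302 to 12976 ± 335 TPM. Processed pseudogenes resemble this gene, so its level carries that uncertainty. TK1, thymidine kinase, fell by 2.73 (SE 0.324, adjusted p = 9.51e-05), from 32 ± 2.59 to 4.42 ± 2.54 TPM, and MITF, the master regulator of the melanocyte lineage, fell by 1.76 (SE 0.299, adjusted p = 0.00171), from 15.9 ± 0.792 to 4.07 ± 1.07 TPM.

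The median fold change of all genes was -0.147 at 48 h and became 0 under median-of-ratios scaling and quantile normalization, so medians of lists that passed camera are followed here by their value relative to all genes. Of 33 ATF4 targets 17 rose, and 20 when adjusted over the list alone (median 0.79, relative 0.94, camera adjusted p = 6.08e-24; adjusted p = 0.0122 with an estimated correlation). SESN2, an inhibitor of mTORC1, rose by 2.88, PPP1R15A by 2.85 (adjusted p = 1.91e-07) and TRIB3 by 2.23 (adjusted p = 1.76e-05). Of 20 tRNA synthetases 4 rose, and 8 rose and 1 fell when adjusted over the list alone (median 0.12, relative 0.27, camera adjusted p = 0.00108; adjusted p = 0.152 with an estimated correlation), led by SARS1 (1.13). Of 22 genes of the unfolded protein response 4 rose, and 5 when adjusted over the list alone (median 0.24, relative 0.385, camera adjusted p = 0.00128; adjusted p = 0.0604 with an estimated correlation), among them HERPUD1 (1.96), XBP1 (1.59) and HYOU1 (1.25). Of 25 NRF2 genes 5 rose and 1 fell, and 8 rose and 1 fell when adjusted over the list alone (median 0.43, relative 0.58, camera adjusted p = 0.000146; adjusted p = 0.308 with an estimated correlation). HMOX1, heme oxygenase, rose by 1.995 (adjusted p = 0.0229) and was lost without untreated replicates 2 or 3 (0.0867, 0.0715) or treated replicates 1 or 2 (0.108, 0.0886). Of 15 AP-1 genes 2 rose, and 4 when adjusted over the list alone (median 0.25, relative 0.40, camera adjusted p = 0.00191; adjusted p = 0.0636 with an estimated correlation), namely ATF3 (1.95) and MAFF (1.1). Of 76 ribosomal proteins 4 rose and 1 fell, also when adjusted over the list alone (median 0.27, relative 0.42, camera adjusted p = 5.05e-17; adjusted p = 0.0604 with an estimated correlation). RPL12 rose by 0.89 and RPS26 fell by 0.81.

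Of 39 E2F targets 25 fell at 48 h, and 1 rose and 36 fell when adjusted over the list alone (median -1.38, relative -1.24, camera adjusted p = 2.83e-21; adjusted p = 0.0458 with an estimated correlation). RRM2 fell by 2.47, TYMS by 2.30 and PCNA, the sliding clamp of replication, by 2.30. Of 40 genes of G2/M and mitosis 34 fell, and all 40 when adjusted over the list alone (median -1.36, relative -1.21, camera adjusted p = 5.81e-28; adjusted p = 0.0412 with an estimated correlation), among them CKS2 (-1.96), the kinesin gene KIF11 (-1.86), MKI67 (-1.84) and NUSAP1 (-1.82). Of 17 heat shock genes 11 fell, and 13 when adjusted over the list alone (median -1.05, relative -0.91, camera adjusted p = 2.34e-09; adjusted p = 0.0124 with an estimated correlation), with HSPA1A at -2.62, HSP90AA1 at -1.77 and DNAJA1 at -1.63. Directions of these 3 lists and of the ATF4 list held under each of the 3 scalings.

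Some genes of lipid synthesis and energy metabolism fell at 48 h, and each of the lists in this paragraph was lost with an estimated correlation. Of 25 genes of cholesterol synthesis 5 fell, also when adjusted over the list alone (median -0.69, relative -0.55, camera adjusted p = 8.33e-05; adjusted p = 0.0604 with an estimated correlation), among them the sterol isomerase gene EBP (-1.26). Of 12 genes of fatty acid synthesis 5 fell, and 6 when adjusted over the list alone (median -0.66, relative -0.51, camera adjusted p = 0.0202; adjusted p = 0.308 with an estimated correlation), including the desaturase SCD (-1.29) and ACSL3 (-1.24). Of 19 glycolytic genes 4 fell, and 5 when adjusted over the list alone (median -0.30, relative -0.16, camera adjusted p = 0.0228; adjusted p = 0.461 with an estimated correlation), with PGAM1 at -1.20 and PKM at -1.04. That list was lost without untreated replicate 3 (0.12), under median-of-ratios scaling (0.107) and under quantile normalization (0.184). Of 37 complex I genes 7 fell, also when adjusted over the list alone (median -0.34, relative -0.19, camera adjusted p = 0.0024; adjusted p = 0.366 with an estimated correlation; 0.0628 and 0.184 under those scalings), including NDUFC2 (-1.03). Of 39 genes of complexes II to V 5 fell, and 11 when adjusted over the list alone (median -0.24, relative -0.10, camera adjusted p = 0.00695; adjusted p = 0.366 with an estimated correlation; 0.345 and 0.386 under those scalings and 0.0581 without untreated replicate 3), including ATP5MC3 (-1.06), UQCR10 (-1.01) and SDHA (-0.78). Of the 13 mitochondrial DNA transcripts 2 rose, also when adjusted over the list alone (median 0.16, relative 0.30, camera adjusted p = 0.0228; adjusted p = 0.64 with an estimated correlation). Its adjusted p was 0.104 without untreated replicate 3, 0.0591 and 0.0513 without treated replicates 1 and 2, and 0.386 under quantile normalization.

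Of 36 genes of lysosomes and autophagy 3 rose and 1 fell at 48 h, and 6 rose and 1 fell when adjusted over the list alone. The median was -0.01 (relative 0.14), positive under median-of-ratios scaling (0.19) and quantile normalization (0.17), the mean was 0.08, and camera placed the list above other genes (camera adjusted p = 0.0253; adjusted p = 0.366 with an estimated correlation; 0.0582 without untreated replicate 1 and 0.0937 without treated replicate 1). WIPI1 (2.56), the autophagy receptor gene SQSTM1 (1.53) and MAP1LC3B (1.33) rose. Of 20 MAPK/ERK genes 3 rose and 1 fell, and 5 rose and 1 fell when adjusted over the list alone (median 0.18, relative 0.33, camera adjusted p = 0.0222; adjusted p = 0.366 with an estimated correlation; 0.0715 without untreated replicate 1 and 0.0816 without treated replicate 3), with DUSP5 up by 2.03. Of 23 hypoxia genes 4 rose, and 4 rose and 3 fell when adjusted over the list alone (camera adjusted p = 0.136, with 0.00387 without untreated replicate 3; median -0.11, mean 0.12, the median turning positive under median-of-ratios scaling and quantile normalization). The 4 were NDRG1 (2.29), SLC2A3 (2.02), VEGFA (1.93) and DDIT4 (1.42).

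No shift of the list was found at 48 h for the others. The p53 targets had 3 of 25 higher and 4 lower, 6 and 4 when adjusted over the list alone (camera adjusted p = 0.121; median -0.06, mean 0.09, median positive under 2 scalings), with GADD45A up by 2.36, BAX, a pore-forming effector of apoptosis, down at -2.03 and PLK2 at -1.66. Genes of dedifferentiated melanoma had 4 of 23 higher and 3 lower, 5 and 7 when adjusted over the list alone (0.813; median -0.11, test upward, median positive under 2 scalings), with THBS1 at -1.99 and CAV1 at -1.95. YAP/TEAD had 2 of 21 higher and 1 lower, 2 and 4 when adjusted over the list alone (0.485). TGF-β and matrix had 3 of 24 higher and 2 lower, 4 and 4 when adjusted over the list alone (0.539; median -0.11, test upward, median positive under 2 scalings), with the gelatinase MMP2 at -2.01. Mitochondrial biogenesis had 1 of 18 higher and 2 lower, 1 and 3 when adjusted over the list alone (0.614). The melanocyte list had MITF as its 1 lower gene of 13, also when adjusted over the list alone (0.987; median -0.14, test upward, turning downward under 2 scalings). Ribosome biogenesis had 1 of 30 lower and 0 when adjusted over the list alone (0.214). The starvation genes had 1 of 12 higher, also when adjusted over the list alone (0.485; median -0.01, test upward, median positive under 2 scalings). Apoptosis regulators had 1 of 24 lower, also when adjusted over the list alone (0.813; median -0.12, test upward, median positive under 2 scalings). The interferon response had 2 of 21 lower, also when adjusted over the list alone (0.266), and antigen presentation 0 of 18, also when adjusted over the list alone (0.689, with limma giving no call).

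Limma called 291 genes higher and 849 lower at 48 h, 215 and 521 of them at least 2-fold, and 3172 had an unadjusted p under 0.05. The largest rises further included IL24 (4.96), S100P (4.22), SPRR2D (3.81), LURAP1L (3.63), LINC00520 (3.57) and OSCAR (3.55). The largest falls were in small RNAs and in the cytokine receptor gene IL7R (-3.16), TMEM14A (-3.04), SCARNA22 (-3.14) and CDKN2C (-2.90), an inhibitor of CDK4 and CDK6, with RNY4 listed at 0 in every treated library. Calls for DHX35-DT (-3.85), SNORA61 (-3.22) and SNORA62, listed at 0 when treated, were lost without treated replicate 3 (0.148, 0.165 and 0.136) and without other single libraries. The split was 25.5% higher, and 49.2% under median-of-ratios scaling (492 higher, 507 lower) and 47.5% under quantile normalization (497 and 550). The count was 614 and 604 without untreated replicates 1 and 2 and 557 without treated replicate 3, and of 108 named genes past the threshold 73 kept the call with each library left out and 67 with every alternative.

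**Figure D3:**
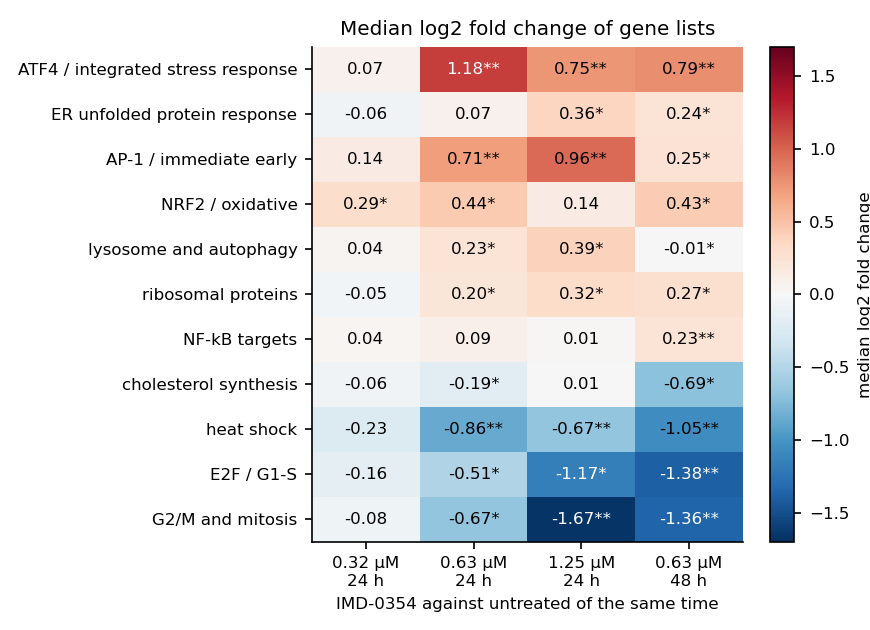
Median log2 fold change of 11 gene lists (rows of the map) in 4 comparisons of IMD-0354 with untreated libraries of the same time (columns), with red for medians above 0 and blue for medians below 0; 1 asterisk marks a camera adjusted p under 0.05 and 2 asterisks one that also holds with an estimated correlation. The G2/M median was -0.08, -0.67, -1.67 and -1.36 and the ATF4 median 0.07, 1.175, 0.75 and 0.79 from left to right; the medians for NF-κB targets and cholesterol synthesis at 1.25 µM turn negative after rescaling and under quantile normalization, and that for lysosomes at 48 h turns positive under median-of-ratios scaling and quantile normalization.

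The NF-κB genes were set apart because IMD-0354 is directed at this pathway. NFKBIA, the inhibitor IκBα and itself an NF-κB target, stood at 24.3 ± 6.32 TPM in untreated cells at 24 h and at 17.2 ± 2.25, 18.4 ± 1.11 and 11.6 ± 0.499 TPM with rising dose. It fell at 1.25 µM by 0.98 (SE 0.274, adjusted p = 0.0299) and was lost without untreated replicates 1 or 2 (0.0668, 0.107), without 1.25 µM replicates 1, 2 or 3 (0.0722, 0.0777, 0.0693) and under quantile normalization (0.0551). At 48 h it was at 17.8 ± 8.29 against 21.1 ± 6.44 TPM (adjusted p = 0.631). Of 24 measured targets 0 passed at 0.32 µM in limma (camera adjusted p = 0.404), 2 rose at 0.63 µM (2 rose and 1 fell when adjusted over the list alone; 0.448), and 4 rose and 3 fell at 1.25 µM, also when adjusted over the list alone (0.641; median 0.01, negative under quantile normalization and rescaling). At 48 h 3 rose, also when adjusted over the list alone (median 0.23, relative 0.38, camera adjusted p = 0.00397; adjusted p = 0.0412 with an estimated correlation), namely the chemokine genes CXCL2 (1.84) and CXCL3 (1.65) and NFKB2 (0.95). CXCL3 was lost without untreated replicates 1 or 3 (0.0505, 0.0685) or treated replicate 3 (0.0591), and NFKB2 without untreated replicates 1 or 3 (0.149, 0.152) or any treated replicate (0.14, 0.0636, 0.113). LIF, a cytokine of the IL-6 family, rose by 2.46 at 1.25 µM (adjusted p = 0.00182). Of 21 pathway components 0, 0, 1 and 1 passed in the 4 comparisons, and 0, 0, 1 and 0 when adjusted over the list alone, with camera adjusted p of 0.803, 0.957, 0.68 and 0.456. The receptor gene TNFRSF1A was at -0.92 at 1.25 µM, a call lost without untreated replicates 1 or 3 (0.0588, 0.0897) or 1.25 µM replicates 1 or 3 (0.0868, 0.112). The kinase and subunit genes IKBKB, CHUK, IKBKG, RELA and NFKB1 did not pass in limma in any of the 4 comparisons. Neither did BRAF, DUSP6, SOX10 and CCND1.

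Markers of other cell types were mostly low, and too few were measured for a list test. POSTN, of fibroblasts, stood at 3.25 ± 1.52 TPM in untreated cells at 24 h and was listed at 0 in every library at 1.25 µM and in treated cells at 48 h. Its fall at 48 h was lost without untreated replicates 1, 2 or 3 (0.0536, 0.178, 0.129) or treated replicates 1, 2 or 3 (0.104, 0.103, 0.129), and that at 0.63 µM for 24 h (-1.59) without replicate 3 (0.162) and others. FBLN1, the other of 2 measured, was below 3 TPM on average in each group. Of 3 keratinocyte genes KRT10 rose by 1.00 at 1.25 µM, from 42.6 ± 3.03 to 86.7 ± 15 TPM, and SFN was at -1.24 at 48 h, a call lost without untreated replicates 1, 2 or 3 (0.148, 0.102, 0.0625) or treated replicates 1 or 3 (0.0549, 0.196). The endothelial EGFL7 was at 0.54 ± 0.596 TPM untreated and did not pass. CD68, the leukocyte gene measured, rose by 1.85 at 48 h, from 0.58 ± 0.903 to 4.25 ± 1.28 TPM, and was lost without untreated replicates 2 or 3 (0.152, 0.117) or treated replicates 1, 2 or 3 (0.0533, 0.087, 0.144). Of 4 metallothionein and zinc export genes 1 rose at 0.63 µM and 3 at 1.25 µM, while limma called 0 at 0.32 µM and 0 at 48 h, counts that were the same when adjusted over the list alone. MT2A stood at 6114 ± 1438 TPM untreated and 9855 ± 764 TPM at 1.25 µM, and its call was lost without 1.25 µM replicate 3 (0.0592) and under quantile normalization (0.339), as was that at 0.63 µM without untreated replicate 2 (0.067) or 0.63 µM replicate 3 (0.104). Of 4 nuclear RNAs, NEAT1 and MALAT1 among them, 0 passed in limma in the 4 comparisons; 1 rose in each when adjusted over the list alone.

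Between doses at 24 h, the step from 0.32 to 0.63 µM raised GDF15 by 4.54 (SE 0.576, adjusted p = 0.00314), DDIT3 by 2.93 (SE 0.356, adjusted p = 0.00257) and IL24 by 2.54. GTPBP2 rose by 2.71 and SOS1, a Ras exchange factor, fell by 1.48, but without 0.63 µM replicate 3 these were at 0.0782 and 0.0572, and without 0.32 µM replicate 3 at 0.0566 and 0.0512. The step from 0.63 to 1.25 µM raised TXNIP by 3.06 (SE 0.536, adjusted p = 0.00875), SPRR2D by 2.98 and SCOC-AS1 by 2.85, and lowered THBS1 at -2.56 (SE 0.249, adjusted p = 0.000109), the centrosome gene CEP152 at -2.33 (SE 0.255, adjusted p = 0.00028) and ABHD15-AS1 at -4.20. Whether reads were assigned by strand is not given in the sources used here, so the antisense genes cannot be separated from genes they overlap. HSPA1A rose by 2.31 at this step (adjusted p = 0.0371), lost without 0.63 µM replicates 1 or 3 (0.0755, 0.112) or 1.25 µM replicates 2 or 3 (0.0602, 0.165). Per µM of dose, GDF15 rose by 4.75 (SE 0.441, adjusted p = 4.6e-06), IL24 by 4.61 (adjusted p = 1.34e-07), S100P by 4.28 and DDIT3 by 3.44 (adjusted p = 9.69e-07). Limma called 60 genes higher and 23 lower at the lower step, 70 and 156 at the upper step, and 997 rising and 1194 falling with dose. In these tests 2082, 2299 and 4258 genes had an unadjusted p under 0.05. With only the compared groups in the fit both steps gave 0 genes. The lower step gave 41, 29, 51 and 18 without 0.32 µM replicates 1 and 3 and 0.63 µM replicates 1 and 3. The upper step gave 89 and 107 without 0.63 µM replicates 1 and 2 and 82 without 1.25 µM replicate 3, and the trend 1325 without 1.25 µM replicate 3. Rescaling moved the lower step from 72.3% to 53.8% higher (42 and 36), and quantile normalization the upper from 31% to 42.1% higher (112 and 154).

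The 24 h doses shared the untreated libraries, and 3 controls are too few to split, so part of any likeness may come from them. At 0.63 and 1.25 µM, GDF15, DDIT3, PPP1R15A and FTH1 were among 152 genes called higher in both, where independent lists would share 10.0, and CCNB1 among 96 called lower in both, where 7.82 would be shared. Only 1 gene was called in opposite directions. Across genes r was 0.661 for these doses, 0.485 for 0.32 and 0.63 µM and 0.405 for 0.32 and 1.25 µM, against 0.502 in simulations of unchanged groups. The covariance was 0.311, 0.152 and 0.149 against 0.112 simulated, a difference of 0.198, 0.0400 and 0.0372. The simulations gave a gene the same spread in all groups. Untreated 24 h replicates 2 and 3 had the lowest mean correlations with their group (0.907 and 0.920). The small differences for pairs with 0.32 µM may therefore come from the shared controls. The comparisons of 1.25 µM at 24 h and 0.63 µM at 48 h shared no library. IL24, GDF15, S100P and DDIT3 rose and CDK1, TYMS, THBS1 and CAV1 fell in both. In all, 178 genes were higher in both (14.4 for independent lists), 391 lower in both (54.0) and 0 opposite (limma; r = 0.458 and Spearman's rho = 0.411 across genes).

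**Figure D4:**
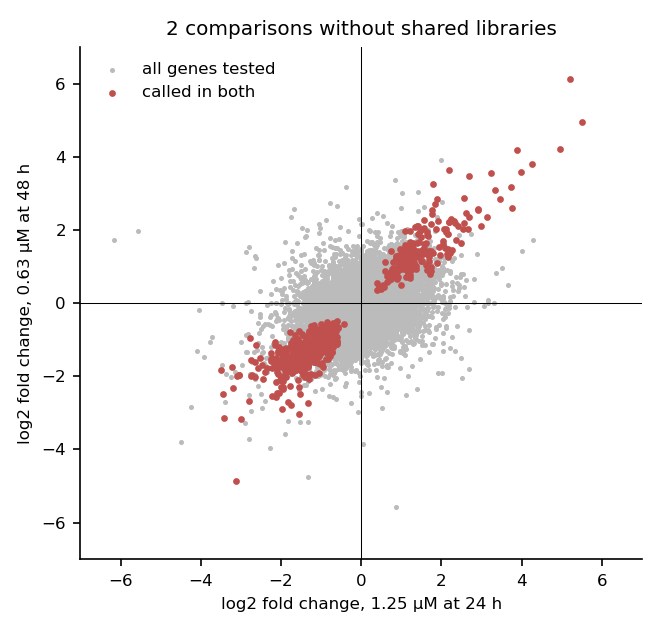
Log2 fold change of each tested gene at 0.63 µM for 48 h (y axis) against that at 1.25 µM for 24 h (x axis), each against untreated libraries of its own time, with genes called in both in red and all 14936 tested genes in grey. Of the genes in red, 178 were higher and 391 lower in both.

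For 0.63 µM at 24 and 48 h, which also shared no library, 79 genes including GDF15, IL24, DDIT3 and FTH1 were higher in both (3.96 for independent lists), 56 lower (6.99) and 1 opposite, with r = 0.322 and rho = 0.303 across genes. The test of the difference between the times called 2 genes with a more positive and 3 with a more negative effect at 48 h, with 1784 at an unadjusted p under 0.05. HSPA5 had an effect higher at 48 h by 1.62 (SE 0.240, adjusted p = 0.0217), CAV1 differed by -1.48 (SE 0.186, adjusted p = 0.00465) and CKS1B, a partner of CDKs, by -1.25 (SE 0.198, adjusted p = 0.0361). HSPA5 and CKS1B were lost without several single libraries, while CAV1 kept the call with each library left out. The count was 0 with only these groups in the fit. It was 2 without untreated 24 h replicate 1, 0.63 µM 24 h replicates 1 or 2, untreated 48 h replicates 1 or 3, or 0.63 µM 48 h replicates 2 or 3, and 10, 18 and 13 without untreated 24 h replicates 2 and 3 and 0.63 µM 24 h replicate 3.

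Untreated cells at 48 h differed from those at 24 h in 2 genes by limma, ENSG00000248155 and ENSG00000252236, both lower at 48 h and both among the 4 named at 0.32 µM; 1181 genes had an unadjusted p under 0.05. DDIT3 stood at 14.9 ± 3.06 and 12.2 ± 3.16 TPM and MKI67 at 111 ± 31.8 and 138 ± 20.2 TPM at 24 and 48 h. The count was 1 without untreated 24 h replicate 2 or any of the untreated 48 h replicates, and 0 with only these groups in the fit or at a minimum of 5 TPM.

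Lists of genes also moved between the untreated groups, with no member past the test over all genes in limma. Lower at 48 h were heat shock genes (17; 0 when adjusted over the list alone; median -0.40, camera adjusted p = 0.00108; adjusted p = 0.193 with an estimated correlation), genes of the unfolded protein response (22; 1 lower when adjusted over the list alone; median -0.31; 0.00158; 0.193) and ribosome biogenesis (30; 2 lower; median -0.19; 0.00158; 0.682). Higher were glycolysis (19; 0; median 0.11; 0.00818; 0.943), fatty acid synthesis (12; 2 higher; median 0.18; 0.0257; 0.682) and complex I (37; 0; median 0.14; 0.0257; 0.943). All kept their direction and call under each of the 3 scalings, and heat shock and the unfolded protein response also with each library left out. Ribosome biogenesis was lost without untreated 24 h replicate 1 (0.0841) or 48 h replicate 3 (0.0986), and fatty acid synthesis without 24 h replicates 1 or 2 (0.447, 0.08) or 48 h replicate 2 (0.134). Without 24 h replicate 2 glycolysis (0.795, median -0.06) and complex I (0.953, median -0.02) were lost, as they were without 48 h replicate 3 (0.116 and 0.0661).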

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

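The differences below were chosen by the test of the effect of 0.63 µM at 48 h minus that at 24 h, and among the tests of patterns here none was chosen only after the result was seen, except that the library pair with the lowest correlation and the rescaling without the chromosome 21 transcripts were added after seeing the data, and that scalings and left-out libraries were run on the lists of this difference after its result was seen.

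A difference between the times met the threshold for 5 genes, of which 4 are given. The effect on HSPA5 was higher at 48 h by 1.621 (0.45 at 24 h and 2.07 at 48 h), and that on the small RNA gene ENSG00000252236 by 2.862 (SE 0.363, adjusted p = 0.00465; -2.86 at 24 h and 0 at 48 h). The last gene was listed at 0 in every group but untreated cells at 24 h. No effect at 48 h could be measured for it, and its difference rests on its detection in those untreated libraries alone. The effect on CAV1 differed by -1.476 (-0.47 and -1.95) and on CKS1B by -1.252 (0.34 and -0.92). All these differences cross the divide in running numbers. Without untreated 24 h replicate 1 the adjusted p was 0.0652 for HSPA5 and 0.0869 for CKS1B.

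Among gene lists the same test gave the camera adjusted p below, each with the medians at 24 and 48 h relative to all genes, whose own medians were 0.004 and -0.147. They were 6.11e-09 for E2F targets (-0.515 and -1.24), 8.41e-09 for G2/M and mitosis (-0.67 and -1.21), 9.35e-07 for complex I (0.17 and -0.19), 3.37e-07 for complexes II to V (0.18 and -0.10), 0.000191 for glycolysis (0.16 and -0.16), 0.0372 for fatty acid synthesis (0.02 and -0.51), 0.00261 for dedifferentiated melanoma (0.27 and 0.04), 0.00261 for YAP/TEAD (0.33 and -0.28), 0.000267 for ribosomal proteins (0.20 and 0.42) and 0.0351 for the unfolded protein response (0.07 and 0.385). The untreated groups moved too. From 24 to 48 h the unfolded protein response was lower in them (median -0.31). Glycolysis (0.11), fatty acid synthesis (0.18) and complex I (0.14) were higher. Each went against the direction of its difference in effect, so those differences may hold a change of the untreated cells. These untreated calls were lost with an estimated correlation. Without untreated 24 h replicate 2 the untreated rise was also lost for glycolysis and complex I. Both differences kept the call without it (0.00668 and 6.95e-05). Their medians, not taken relative to all genes, went from -0.717 to -0.34 and from -0.529 to -0.36. All directions held under the 3 scalings. Fatty acid synthesis was lost under median-of-ratios scaling (0.0527) and ribosomal proteins under quantile normalization (0.229). Leaving out libraries ended the unfolded protein response (untreated 24 h replicate 3, 0.0742; 0.63 µM 24 h replicate 3, 0.0698; 0.63 µM 48 h replicate 2, 0.0835) and ribosomal proteins (0.63 µM 24 h replicate 2, 0.0941). It also ended fatty acid synthesis, without untreated 24 h replicates 1 or 2 (0.171, 0.0532), 0.63 µM 24 h replicates 1 or 3 (0.0547, 0.0518), untreated 48 h replicate 2 (0.0906) or 0.63 µM 48 h replicate 3 (0.0803). With an estimated correlation the adjusted p was 0.278 for E2F targets, complex I, complexes II to V, dedifferentiated melanoma, YAP/TEAD and the unfolded protein response, 0.3 for G2/M and glycolysis, 0.38 for fatty acid synthesis and 0.464 for ribosomal proteins, so each call was lost. For the count of 5 genes, 6 of 100 splits of the libraries gave as many and the highest other split gave 175. A split that mixes the libraries of 1 time leaves the treatment effect at the other time in place. These splits therefore give no value for an unchanged difference, and the test, judged void after its value was seen, does not decide on chance.

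The E2F and G2/M lists were lower at 1.25 µM for 24 h and at 0.63 µM for 48 h, and technical explanations were weighed. Rescaling without the chromosome 21 transcripts left the highest of the 4 medians at -1.225. Without the 2 least correlated libraries the higher median at 1.25 µM was -1.188. Against 10000 random lists matched on expression the highest median was -1.165, where the central 95% for E2F targets at 1.25 µM ran from -0.289 to 0.172. These values argue against expression level as the whole cause and against those 2 libraries as the cause at 1.25 µM. Rescaling, with 1 factor per library, speaks only against the share's effect on scaling. At 48 h no test on libraries that stand apart was made, though both lists kept the call there and at 1.25 µM with each library left out. Fewer dividing cells with IMD-0354 was not tested and stays open as a hypothesis.

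At 48 h more genes were lower than higher, with 25.5% of calls higher. Among genes with at least 20 TPM on average 19.875% were higher (127 of 639), which argues against lost detection of low genes. The chromosome 21 share was alike at 48 h (23.5% and 23.6%), so rescaling (25.042%) could hardly move the split and tests little. Median-of-ratios scaling gave 49.249%, but that scaling centres the genes by its construction, so this test is void and a general shift cannot be told apart from a difference in scaling. TPM holds no depth with which to decide.

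For 3 libraries against 3 the 10 splits are too few for a share under 0.05. The real count and the highest of the other splits were 4 and 6 at 0.32 µM (2 of 10 splits as high), 326 and 5 at 0.63 µM, 1688 and 2 at 1.25 µM, 1140 and 1 at 48 h, 83 and 4 for 0.63 against 0.32 µM, and 226 and 3 for 1.25 against 0.63 µM, each of these 5 with 1 of 10 splits as high. For untreated cells at 48 against 24 h they were 2 and 2 (2 of 10). The dose trend called 2191 genes, the highest of the other splits 629, and 1 of 100 splits was as high. This argues against a chance assignment of these libraries to doses for that count. It cannot speak to differences between cultures, since the libraries of a group may be repeats of 1 culture. Nor can it speak to the running numbers.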

How the results depend on the processing

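Leaving out the library pairs, rescaling without the chromosome 21 transcripts and the estimates under them were tests chosen only after the result was seen. Of 301 values for counts and agreements under alternatives 227 stayed within 1.5 times (or within the spread) and 74 moved, over 14 results. Of 2728 for lists 2475 kept their direction and side of the threshold, 108 lost the call, 36 gained it, 108 without a call moved and 1 turned; of 10317 for named genes these were 8975, 1145, 62, 135 and 0. The list that turned was the mitochondrial DNA transcripts at 0.63 µM for 24 h without the 2 least correlated libraries (adjusted p = 0.927). Counts are given against 4, 326 and 1688 genes at 0.32, 0.63 and 1.25 µM, 1140 at 48 h, 83 and 226 for the lower and upper dose step, 2191 for the trend, 5 for the difference between times and 2 for untreated cells over time. Of 48 list calls 12 were left with an estimated correlation.

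With only the compared groups in the fit limma called 0 genes at 0.32 µM, 0 at 0.63 µM, 171 at 1.25 µM, 0 for both dose steps, 0 for the difference between times and 0 over time, where fewer residual degrees of freedom are part of the setting; unadjusted counts with all groups were 912, 2672, 3838, 2082, 2299, 1784 and 1181. With no filter the counts were 14 at 0.32 µM, 175 at 0.63 µM, 8 for the difference and 6 over time, and with a minimum of 5 TPM limma called 0 at 0.32 µM and 0 over time. A pseudocount of 0.1 gave 1 at 0.32 µM, 1 over time and r = 0.230 for 24 against 48 h (0.322 in the main analysis). Without the mean-variance trend 11, 200 and 2 were called at 0.32 µM, at 0.63 µM and for the difference. Library weights gave 2312 at 48 h, 126 and 350 for the steps, 151 for the difference and 4 over time. The 3 scalings each gave 3 for the difference. Without the 2 least correlated libraries, which leaves 1 untreated library at 24 h that is assumed to vary like the other groups, counts were 0 at 0.32 µM, 21 at 0.63 µM (15 shared), 493 at 1.25 µM, 199 and 366 for the steps, 1088 for the trend, 3 for the difference and 0 over time; without the 2 picked by eye they were 1 at 0.32 µM, 35 at 0.63 µM, 392 for the upper step, 25 for the difference and 1 over time. Apart from smaller numbers of genes or libraries, the cause was not tested.

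Leaving out each library gave 1 to 4 genes at 0.32 µM, 51 to 490 at 0.63 µM (without 0.63 µM replicate 3 and untreated replicate 3), 960 to 1676 at 1.25 µM (lowest without 1.25 µM replicate 3), 557 to 879 at 48 h (lowest without treated replicate 3), 18 to 64 and 82 to 190 for the steps, 1325 to 2211 for the trend, 2 to 18 for the difference, 1 to 3 over time and 46 to 51 list calls. The correlation of 24 and 48 h effects ran from 0.264 to 0.346, and those between doses from 0.406 to 0.623, 0.343 to 0.537 and 0.604 to 0.730. With the replicate number as a block the counts were 3, 420, 1767, 1272, 121, 287, 2298, 4 and 3 in the order above. The numbers were not taken to pair the libraries. The reason was that in 0 of 15 pairs of groups was every correlation above 0.1 (lowest -0.0927, highest 0.115). In 2 pairs, though, all 6 libraries correlated best with their own number, and in the other pairs from 1 to 5 did. Those numbered 3 also deviated together in the test on mitochondrial share. These values point to some structure shared by libraries of the same number, though its correlations were small. The main fit leaves it out. TPM keeps no depth, so what depth limits could not be measured.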

Other observations

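The tests on the number 3 and on the histone list were chosen only after the result was seen, as were the lists of snoRNA hosts, decay factors, iron handling and histones themselves. For the test on decay the rule for exclusion was made stricter after its value was seen.

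Some non-coding hosts of small nucleolar RNAs rose with IMD-0354 and others fell. At 0.32 µM for 24 h the list of these hosts did not pass camera (median 0.037, adjusted p = 0.993). Of 22 measured, 3 rose at 0.63 µM (5 rose and 1 fell when adjusted over the list alone; camera adjusted p = 0.0132; adjusted p = 0.118 with an estimated correlation), 8 rose and 3 fell at 1.25 µM (9 and 3; 0.00928; 0.0808), and 7 rose and 1 fell at 48 h (11 and 1; median 0.45; 1.06e-08; 0.00253). Such transcripts are degraded by nonsense-mediated decay, so less decay was tested as a candidate explanation. The 8 decay factors, whose own transcripts are targets of that decay, had medians of 0.19 at 1.25 µM and -0.151 at 48 h, where the median of all genes was -0.147. The rule written beforehand, a lower median below 0, would have excluded less decay. The rule added later, that the list must also lie below other genes by camera, was not met (camera adjusted p = 0.576 and 0.874), and at 48 h 3 members were higher and 5 lower, with a positive median under median-of-ratios scaling (0.05) and quantile normalization (0.055). Less decay was therefore left open.

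Of 34 replication-dependent histone genes 2 fell at 0.63 µM (7 when adjusted over the list alone; median -0.64; camera adjusted p = 6.92e-05; adjusted p = 0.118 with an estimated correlation), 1 rose and 11 fell at 1.25 µM (1 and 12; median -0.78; 3.64e-07; 0.0808), and 1 rose and 7 fell at 48 h (1 and 9; median -0.85; 0.00244; 0.237). Fewer cells in S phase was set against the higher of the last 2 medians, -0.777. The list was chosen because it was lower, so this test is void and the explanation stays open; it was judged void after its value was seen. The list is lost with an estimated correlation, and these genes resemble one another in sequence. Levels of histone transcripts carry the limit on capture given above. At 0.32 µM for 24 h neither this list nor that of iron handling passed camera (adjusted p = 0.993 and 0.149). Of 8 iron handling genes 2 rose at 0.63 µM (camera adjusted p = 0.0209; 0.118 with an estimated correlation; lost at 0.0676 without untreated replicate 1), 2 at 1.25 µM (0.00928; 0.0808), and 3 rose and 1 fell at 48 h (0.00119; 0.0436).

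The library numbered 3 had the lowest share of mitochondrial transcripts in 6 of 6 groups (exact p = 0.00137 for a number set beforehand and 0.00412 for any number). With mitochondrial genes left out, 2 of all possible choices of 1 library per group, the real one included, correlated as well in their deviations as the libraries numbered 3. A handling step shared by those libraries may be the explanation; no biological explanation was tested. The labels name no batch, and the meaning of the running numbers in them is not stated.

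The 4 long non-coding transcripts of the minus strand on chromosome 21 (ENSG00000280614, 8393419 to 8394341; ENSG00000280800, 8210384 to 8211306; ENSG00000281181, 8437629 to 8438551; ENSG00000281383, 8254592 to 8255514) together held from 13.1% to 24.8% of TPM per library. The name long non-coding is that of the annotation. The mean over all libraries was 51032 TPM for each of ENSG00000280614, ENSG00000280800 and ENSG00000281181, and 36544 TPM for ENSG00000281383. With identical means the division of reads between them is uncertain, and whether they are separate transcripts was not tested. Group means of the joint share at 24 h were 18.1% ± 3.23 untreated, 19.4% ± 0.570 at 0.32 µM, 14.3% ± 0.0853 at 0.63 µM and 15% ± 2.03 at 1.25 µM. At 48 h they were 23.5% ± 1.05 untreated and 23.6% ± 1.11 at 0.63 µM. The groups set apart by running number had the lowest means. The first principal component held 18.3% and the second 9.92% of the variance.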
